A study of Mus musculus with 9 samples.

How the data were processed

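The series holds low-input RNA sequencing of sorted mouse bone marrow HSCs, 1500 cells per library, in 3 groups of 3 libraries. Per the labels' protocol, marrow was flushed from femora and tibiae, red cells were lysed, polyadenylated RNA of the sorted cells was reverse transcribed and enriched with 12 PCR cycles, and libraries made with a transposase kit were sequenced as paired reads on a NovaSeq. The labels name no surface markers for the sort, no sex, no batch and no source animal for a library. The labels state no strand-specific step for this kit, so genes that overlap on opposite strands cannot be told apart.

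The submitters' processing notes list Trim Galore 0.6.2, STAR 2.6.1d, HTSeq 0.10.0 and edgeR 3.24.3 and the build mm10, without saying which step made which values. The authors deposited a table of estimated counts per gene and a table of TPM (transcript abundance scaled for length and depth) for the same 9 libraries. The deposited estimated counts are not scaled between libraries, and 48.2% of values are whole to within 1e-06, whereas counting whole reads would give whole values throughout. The step that made the fractional values is therefore not known, and reads that fit several genes were probably shared between them by a model. The deposited TPM values are scaled within each library for transcript length and depth. Only genes with a summed count of at least 5 over the 9 libraries are listed, so the TPM columns sum to between 937835 and 948801. Of the listed genes, 19437 matched an identifier in the GENCODE M21 annotation of mm10, which gave the coordinates (1-based, gene bounds), and 17 did not.

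Estimated counts were rounded to whole numbers. Genes were tested in R 4.3.3 with edgeR 4.0.16, using its quasi-likelihood test on all 9 libraries in 1 fit with a mean per group, TMM scaling factors and edgeR's default filter on low counts, which kept 14461 of 19454 genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fitting all 9 libraries together pools the estimate of spread, since 3 libraries per group give little by themselves. CPM values use the TMM factors, which ranged from 0.931 to 1.14. The total count per library was 16096276 to 25360256, so a count of 0 (floor of 3 counts) allows up to 0.118 to 0.186 CPM, and this floor covers counting error only because PCR copies are not independent molecules. With 3 libraries against 3, a rank-based exact permutation test of a single value could not go below 0.10, so none was used.

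Gene lists were fixed before the data were examined, from general knowledge of mouse haematopoiesis. Of 1061 listed entries 12 matched no gene in the table. They cover HSC identity and quiescence, HSC ageing, lymphoid priming, myeloid differentiation, megakaryocytes and platelets, and erythroid cells. Lists for other cells cover neutrophil granules, T and NK cells, B and plasma cells, monocytes and macrophages, stroma, endothelium and bone, and basophil, eosinophil and mast cells. Lists for signalling cover type I interferon, NF-kB, immediate-early and dissociation genes, glucocorticoid response and neural receptors. Lists for growth and damage cover S phase, mitosis, G1 control, p53 targets, and chromatin and DNA methylation regulators. Lists for metabolism cover nuclear oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, glycolysis and hypoxia, polyamines and eIF5A, autophagy and lysosome, the unfolded protein response, and NRF2 targets. The rest cover the proteasome, cytosolic ribosomal proteins, ribosome biogenesis, cholesterol synthesis and adhesion. Sex-linked genes were a check only, so 35 of 36 lists were tested. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, which compares its genes with all other tested genes, and adjusted over the 35 lists. Estimating that correlation, and fry, which asks whether a list's genes move 1 way on balance, were alternatives. Some genes stand in several lists, such as Lyz2 in the myeloid and monocyte lists.

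Genes named in the text were chosen by a rule fixed in advance. For each comparison it takes the 8 higher and 8 lower genes with the largest fold change among those past the threshold whose libraries do not overlap and whose mean is at least 5 CPM. It leaves out unnamed gene models, pseudogenes and antigen receptor segments. It adds up to 4 members of each list with the smallest p and 33 focus genes, of which 32 were tested. Every gene given a value falls under it for the comparison in which it is named, except Actb, which was chosen after its values were seen.

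Replicate numbers could pair libraries across groups. Across the 9 pairs of libraries with the same number, residual expression correlated at -0.0365 to 0.0526, none above 0.1, so the fit took no block and a fit with the replicate block is an alternative. The libraries of a group differed beyond counting noise, with a mean chi-squared per gene of 2.45 to 7.75. Fold changes of the first and second comparisons share the inhibition libraries, so their correlation and overlap were set beside 20 simulations of 3 unchanged groups with the same means, spread and library sizes.

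The scripts were tested on simulated data with known changes before use. For inhibition against control, edgeR called 18.8% of genes changed 1.2-fold, 45.8% of those changed 1.5-fold, 82.0% of those changed 2-fold and 98.0% of those changed 4-fold, and 0.0221% of unchanged genes, among 13796 tested. For spermidine against inhibition it called 22.9%, 50.0%, 78.0% and 98.0%, and 0.0441% of unchanged genes. In a simulation with 1 shifted list, camera called that list and none of the others. Genes were drawn independently there, so it does not test calls for lists whose genes vary together.

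Alternatives fixed before the data were examined were other scaling (RLE factors, or library size alone), DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, a strict filter of at least 5 CPM in 3 libraries, only the groups compared, the replicate block, a minimum change of 2-fold, limma on log2(TPM + 1) with and without a filter at a mean TPM of 1, limma on log2(TPM + 0.1), and leaving out each library in turn. Because libraries of a group differed so little, a spread fixed at 0.1 or 0.2 (the coefficient of variation) and a fit without immunoglobulin, other-cell and olfactory or vomeronasal receptor genes were added after seeing the data.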

Results

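Haematopoietic stem cells (HSCs), the rare self-renewing cells of the bone marrow from which all blood lineages arise, were sorted from wild-type mice and profiled by low-input RNA sequencing. In this assay the polyadenylated RNA of a small number of cells is copied into cDNA and enriched by PCR before sequencing. Each library started from 1500 sorted cells and 12 PCR cycles, per the labels' protocol. The 9 libraries fall into 3 groups of 3. The control group had no brain intervention named in its labels. In the inhibition group, neurons of the mPFC and PAG brain regions (usually read as the medial prefrontal cortex and the periaqueductal grey) were silenced by chemogenetic inhibition, in which chosen neurons carry a designed receptor that lowers their activity when a matching drug is given. The spermidine group had the same inhibition and received spermidine, a polyamine made by animal cells and by gut bacteria. The series' title places these libraries in a study of psychological stress, HSC ageing and loss of spermidine.

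Total counts were 17691292, 19834970 and 20432803 in the control libraries, 17231844, 25360256 and 21494423 in the inhibition libraries, and 22097230, 22467276 and 16096276 in the spermidine libraries. Of 19454 genes listed, 14461 had enough counts to be tested. Log2 expression correlated across genes at 0.989 to 0.993 between libraries of a group, at 0.896 to 0.903 between control and the other groups, and at 0.970 to 0.972 between the inhibition and spermidine groups. The first principal component held 74.5% of the variance and separated control from both other groups, and the second held 15.0% and separated the inhibition from the spermidine group. The typical gene varied by 4.07% between libraries of a group beyond counting noise. The edgeR p-values measure only the spread between libraries. The labels do not say whether the libraries of a group came from different mice, so this spread may be technical. Camera p-values, which compare a list with all other tested genes, also rest on the spread across genes and the preset correlation of 0.01. With that correlation estimated, the lists that still passed did so at larger camera adjusted p-values. These were 0.0453 throughout for inhibition against control, 0.00772 to 0.0307 for spermidine against inhibition, and 0.0212 to 0.0446 for spermidine against control. Expression is given as CPM (counts scaled to a common library total), as the mean of 3 libraries with its SD where given, and fold changes come from edgeR with their standard error (SE).

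The first comparison, inhibition against control, asks how HSC expression differed between libraries with these brain regions silenced and control. The library names mark both inhibition groups as AAV, a viral gene carrier, and control as Ctrl. The labels name no brain intervention for control, so effects of the virus or the drug cannot be told apart from those of silencing. Genes of megakaryocytes and platelets were lower, and genes of mature neutrophils, lymphoid cells and plasma cells were higher. Pf4, platelet factor 4, fell from 2673 CPM (SD 7.88) in control to 104 CPM (SD 3.47) with inhibition (log2 fold change -4.69, SE 0.034, n = 3 per group). Car1, an erythroid carbonic anhydrase, fell from 1597 to 29.7 CPM (log2 fold change -5.75, SE 0.033). Ngp, a neutrophil granule protein, rose from 110.5 to 10520 CPM (log2 fold change 6.57, SE 0.036). Hlf, a transcription factor of HSCs, rose from 2.50 to 22.3 CPM (log2 fold change 3.15, SE 0.089).

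In total 5240 genes were higher and 5227 lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg over 14461 genes), and of these 2163 and 2027 changed at least 2-fold. The libraries of the groups did not overlap for 74.5% of genes, where chance gives 10%. Without the immunoglobulin genes, the lists of other cell types and the olfactory and vomeronasal receptor genes, a setting chosen after seeing the data, 4942 genes were higher and 5081 lower. With limma on log2(TPM + 1) the split was 3871 higher and 3427 lower. Scaling by total count alone, in place of trimmed-mean (TMM) scaling, moved the median gene by 0.0019 on the log2 scale in this comparison, and by 0.26 in both comparisons with the spermidine group.

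Pf4 (ENSMUSG00000029373, chromosome 5, positions 90772435 to 90773383, plus strand), Car1 (ENSMUSG00000027556, chromosome 3, positions 14766216 to 14808368, minus strand), Hlf (ENSMUSG00000003949, chromosome 11, positions 90336536 to 90390895, minus strand) and Ngp (ENSMUSG00000032484, chromosome 9, positions 110419747 to 110423012, plus strand) are protein-coding genes, placed here by their gene bounds in the GENCODE M21 annotation of mm10. By the rule fixed in advance, the 8 genes with the largest rise were Jchain, Tpm3-rs7, Prok2, Stfa1, Ly6g, Ltf, Ngp and Chil1, with log2 fold changes from 9.51 (SE 0.082) for Jchain, the chain that joins antibody units, to 6.52 (SE 0.087) for Chil1. Tpm3-rs7 is a close copy of Tpm3 and can share its reads, so its value is uncertain. The 8 with the largest fall were Fbxl13, Prss50, Car1, Pdzph1, Ptpn14, Samd14, Fam187b and Fam161b, from -6.99 (SE 0.16) for Fbxl13 to -4.86 (SE 0.088) for Fam161b.

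**Figure D1:**
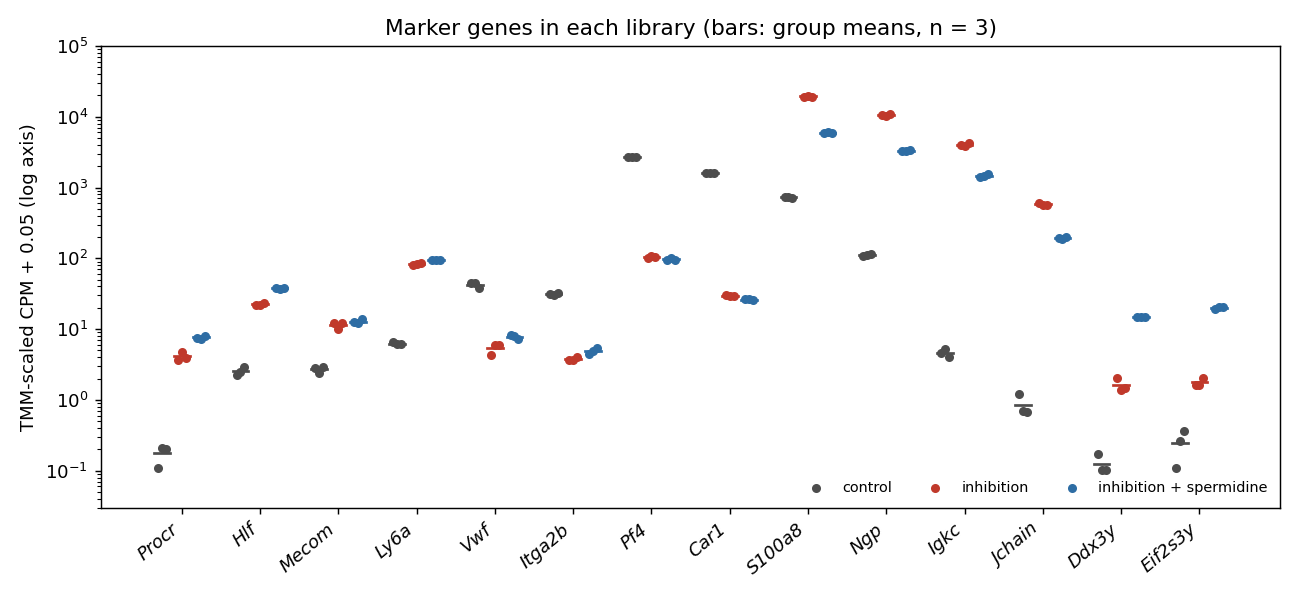
Expression of 14 marker genes in each of the 9 libraries, as CPM plus 0.05 on a log axis, with points for libraries and bars for the mean of 3. Pf4 falls from 2673 CPM in control to 104 CPM with inhibition, and the libraries of a group lie close together.

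Among the 25 measured genes of the megakaryocyte and platelet list, 22 fell, 2 rose and 1 did not pass, with a median log2 fold change of -1.66 (camera adjusted p = 6.48e-07). Besides Pf4, these included Gp1bb, a subunit of the von Willebrand factor receptor (log2 fold change -3.32, SE 0.051), F2rl2 (log2 fold change -3.09, SE 0.053), Vwf, von Willebrand factor (log2 fold change -2.96, SE 0.096), and Itga2b, the integrin chain CD41 (log2 fold change -3.06, SE 0.083). Selp, P-selectin, was an exception and rose from 2.07 to 9.97 CPM (log2 fold change 2.27, SE 0.15). The erythroid list split, with 7 genes higher and 12 lower of 20, and did not pass (adjusted p = 0.144). Its haemoglobin genes rose, as Hba-a2 (log2 fold change 2.77, SE 0.048) and Hbb-b1 (log2 fold change 2.70, SE 0.043), each of which can share reads with its near-identical copy, while Car1 and Blvrb (log2 fold change -2.81, SE 0.049) and Gata1, a transcription factor of erythroid and megakaryocytic cells (log2 fold change -2.92, SE 0.096), fell.

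All 15 neutrophil granule genes changed, 14 upward and 1 downward, with a median of 5.73 (camera adjusted p = 1.23e-08; adjusted p = 0.0453 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits, reached 19330 and 12160 CPM from 729 and 274 CPM (log2 fold change 4.73, SE 0.031 and log2 fold change 5.47, SE 0.032), and Camp, an antimicrobial peptide, rose with them (log2 fold change 5.82, SE 0.032). The list took 4.80% of all counts (SD 0.0621) with inhibition and 0.157% (SD 0.00148) in control. In the myeloid differentiation list 18 of 20 genes rose and 1 fell, with a median of 1.65 (camera adjusted p = 7.6e-08), including Lyz2, lysozyme (log2 fold change 3.63, SE 0.029), and Mpo, myeloperoxidase of early myeloid cells (log2 fold change 1.18, SE 0.032), in the same libraries as that neutrophil share. Of the monocyte and macrophage list 11 genes rose and 1 fell of 15 (camera adjusted p = 0.0015), among them Cd14 (log2 fold change 3.09, SE 0.061) and Cd68 (log2 fold change 1.77, SE 0.04).

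Lymphoid genes were higher too. The lymphoid priming list had 17 genes up and 5 down of 23 (median 0.92, camera adjusted p = 0.00292), led by Dntt, the enzyme that adds bases at antigen receptor joints (log2 fold change 5.23, SE 0.076). The B and plasma cell list had 12 up and 3 down of 16 (camera adjusted p = 0.00325). Igkc, the kappa light chain constant region, rose from 4.54 to 4029 CPM (log2 fold change 9.79, SE 0.069), and immunoglobulin genes together took 0.643% of counts (SD 0.0146) against 0.0192% in control (SD 0.000835), a ratio of 33.6. In the T and NK cell list 10 rose and 1 fell of 12 (median 2.46, camera adjusted p = 0.00531), with Klrb1c (log2 fold change 3.96, SE 0.29) up and Lat (log2 fold change -1.12, SE 0.069) down. That call was lost when the correlation between genes was estimated (adjusted p = 0.0596 with an estimated correlation). The stroma, endothelium and bone list had 6 up and 1 down of 13 and did not pass (adjusted p = 0.101, or 0.0464 without inhibition replicate 2), although Emcn, endomucin of blood vessels and of some HSCs, rose (log2 fold change 3.59, SE 0.11). The basophil, eosinophil and mast cell list had 7 up and 4 down of 12 and did not pass (adjusted p = 0.246).

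HSC identity genes moved both ways. Of 32 genes 18 rose, 11 fell and 3 did not pass, and the list as a whole missed the threshold (camera adjusted p = 0.197). Ly6a, the surface antigen Sca-1, rose from 6.21 to 83.5 CPM (log2 fold change 3.75, SE 0.052), as did Ifitm1 (log2 fold change 2.70, SE 0.03) and Mecom, an HSC transcription factor (log2 fold change 2.10, SE 0.12). Procr, the protein C receptor used to mark HSCs, rose from 0.125 to 4.10 CPM (log2 fold change 4.95, SE 0.28). Gata2, another HSC transcription factor, fell from 56.4 to 9.54 CPM (log2 fold change -2.57, SE 0.067), and Mllt3 fell as well (log2 fold change -0.56, SE 0.056). Of the 45 genes listed as higher in aged HSCs, 25 rose and 17 fell, and the list did not pass (adjusted p = 0.406). With fry, under which 34 of 35 lists passed, it pointed up (fry adjusted p = 0.000434). Nupr1 (log2 fold change 1.44, SE 0.048), Clu, clusterin (log2 fold change 1.16, SE 0.062), and Gda (from 11.5 to 70.1 CPM) rose, whereas Slamf1, the antigen CD150 (log2 fold change -2.56, SE 0.068), Vwf and Itga2b fell. For Procr, Selp, Cdkn1c, Jchain, Sc5d, Ddx3y and Kdm5d, the deposited counts and TPM values imply an effective transcript length that differed between the groups by more than 0.5 on the log2 scale, so part of their difference rests on which transcripts were counted.

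Genes of protein synthesis and respiration were lower with inhibition, in the libraries with the higher neutrophil granule share (4.80% against 0.157%) and immunoglobulin share (0.643% against 0.0192%). These libraries also held a lower share of histone counts (0.345% against 0.894% in control), and the labels give no preparation batch, so a difference in preparation between the groups is not excluded. Of 80 cytosolic ribosomal protein genes 78 fell and 1 rose (median -0.54, camera adjusted p = 1.74e-14; adjusted p = 0.195 with an estimated correlation), including Rpsa (log2 fold change -1.17, SE 0.029). All 13 mitochondrially encoded genes fell (median -0.78, camera adjusted p = 9.53e-05; adjusted p = 0.0878 with an estimated correlation), and nuclear genes of oxidative phosphorylation had 50 down and 13 up of 76 (camera adjusted p = 0.00135; adjusted p = 0.371 with an estimated correlation). Ribosome biogenesis and MYC target genes had 28 down and 6 up of 36 (camera adjusted p = 0.00029), with Fbl, fibrillarin, down (log2 fold change -1.43, SE 0.074) and Eif4e up (log2 fold change 0.68, SE 0.031). The type I interferon list had 22 down and 7 up of 34 (camera adjusted p = 0.00423), as with Irf7, a transcription factor of that response (log2 fold change -2.49, SE 0.094), and Xaf1 (log2 fold change -2.04, SE 0.046). Immediate-early and dissociation genes had 20 down and 5 up of 27 (camera adjusted p = 0.00199; adjusted p = 0.121 with an estimated correlation), with Jun (log2 fold change -2.11, SE 0.035) and Egr1 (log2 fold change -2.09, SE 0.07) down.

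Cholesterol synthesis and glycolysis genes were higher. Cholesterol synthesis genes had 19 up and 6 down of 27 (median 0.89, camera adjusted p = 0.00336), for example Sc5d, sterol C5-desaturase (log2 fold change 2.88, SE 0.052). Glycolysis and hypoxia genes had 20 up and 6 down of 29 (camera adjusted p = 0.00325), for example Ldhb, a lactate dehydrogenase chain (log2 fold change 2.31, SE 0.058), and Eno1, enolase (log2 fold change 1.24, SE 0.034). The unfolded protein and integrated stress response list had 24 up and 6 down of 35 (camera adjusted p = 0.00325; adjusted p = 0.088 with an estimated correlation), with Xbp1 up (log2 fold change 1.31, SE 0.035) and Ppp1r15a down (log2 fold change -2.10, SE 0.034). Adhesion and homing genes had 16 up and 7 down of 26 (camera adjusted p = 0.0144; adjusted p = 0.0686 with an estimated correlation), with Rac2, a haematopoietic GTPase, up (log2 fold change 1.38, SE 0.031). All 4 lists rose in libraries with the higher share of neutrophil granule transcripts given above.

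Polyamine genes were followed one by one. The inhibition libraries held the higher neutrophil granule share (4.80% against 0.157% in control), so these values may not be those of HSCs alone. Of 29 polyamine and eIF5A genes 11 rose and 11 fell, and the list did not pass (adjusted p = 0.912). Its median was -0.10 with a test pointing down, while its mean was 0.021. Sat1, which acetylates spermidine for export or breakdown, rose from 151 to 424 CPM (log2 fold change 1.49, SE 0.029), Odc1, the first enzyme of polyamine synthesis, fell (log2 fold change -0.46, SE 0.037), and Eif5a, the protein that is modified with spermidine, rose (log2 fold change 0.44, SE 0.029). Dhps, the enzyme that adds spermidine to eIF5A, did not pass (log2 fold change -0.063, SE 0.094, adjusted p = 0.557). The list of neural receptors had 7 up and 2 down of 13 and did not pass (adjusted p = 0.356). The glucocorticoid targets Fkbp5 (log2 fold change 0.015, SE 0.076, adjusted p = 0.886) and Tsc22d3 (log2 fold change 0.039, SE 0.032, adjusted p = 0.276) did not pass, and their list had 10 up and 7 down of 21 (adjusted p = 0.255).

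The remaining lists did not pass in this comparison. Genes higher and lower were 16 and 8 of 30 for S phase, 13 and 13 of 33 for mitosis, 8 and 7 of 17 for G1 control, and 11 and 13 of 28 for p53 targets. They were 8 and 15 of 29 for fatty acid oxidation, 29 and 16 of 54 for autophagy and lysosome, 16 and 13 of 32 for NRF2 targets, and 19 and 9 of 36 for the proteasome. They were 19 and 12 of 33 for NF-kB signalling and 11 and 9 of 29 for chromatin regulators. Their camera adjusted p-values lay between 0.152 and 0.912. For mitosis the median (-0.069) and the mean (-0.00098) lay below 0 while the test pointed up. Cpt1a, which brings fatty acids into mitochondria, fell (log2 fold change -0.99, SE 0.051). Adjusted over the list alone, the counts of the lists were as given over all genes, except 29 lower for ribosome biogenesis, 5 higher for stroma, 14 lower for p53 targets and 20 higher for the proteasome. In the check of sex-linked genes, Uty (log2 fold change -4.39, SE 0.064) and Kdm5d (log2 fold change -1.40, SE 0.094) fell, and Ddx3y (log2 fold change 4.27, SE 0.38) and Eif2s3y (log2 fold change 3.06, SE 0.31) rose.

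**Figure D2:**
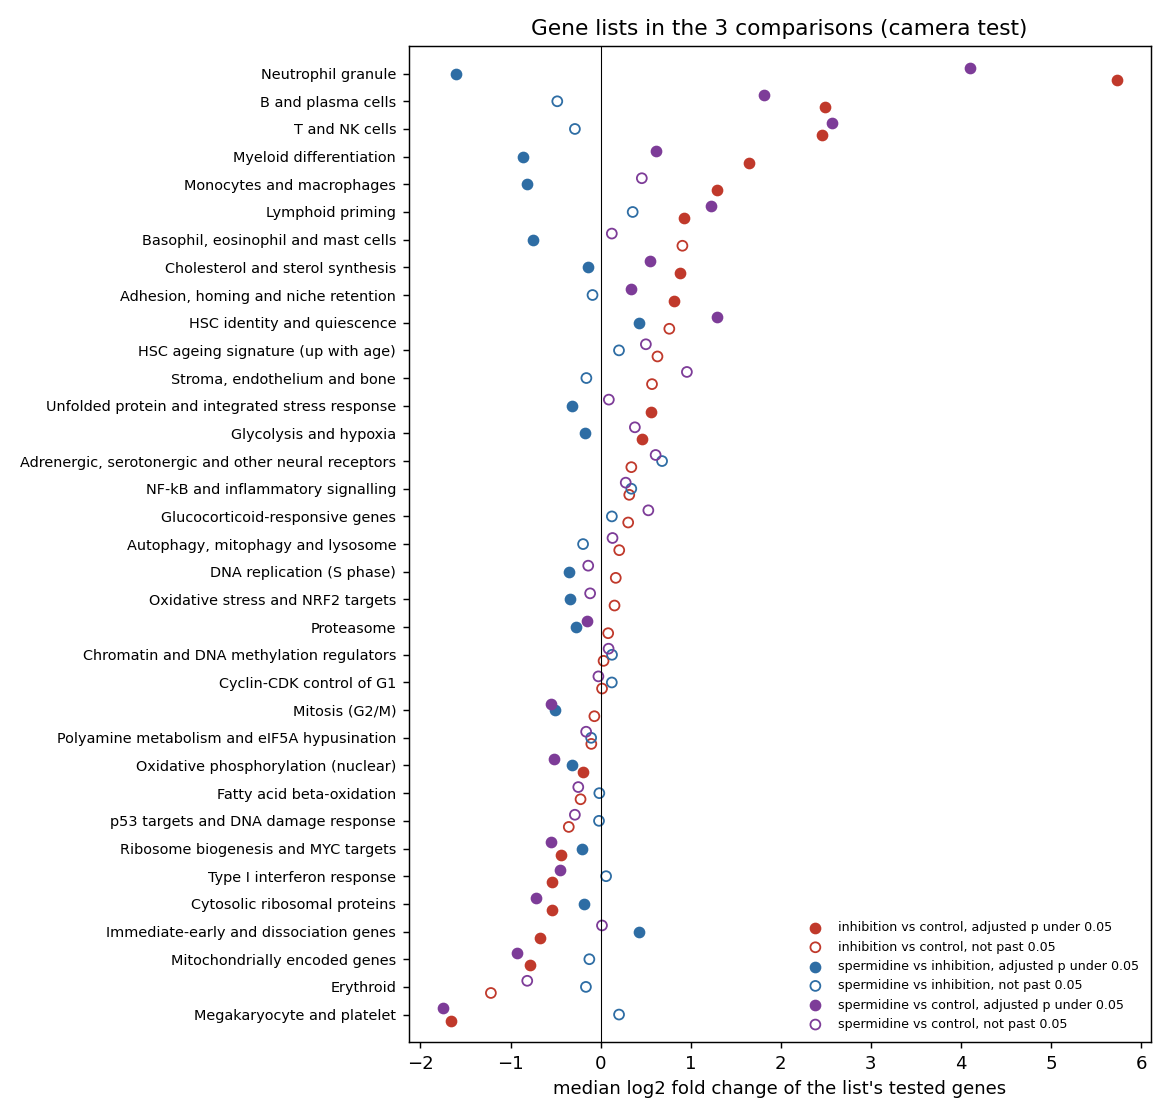
Median log2 fold change of the tested genes of each of 35 gene lists in the 3 comparisons, filled where the camera adjusted p is under 0.05. The neutrophil granule list lies at 5.73 for inhibition against control and at -1.60 for spermidine against inhibition.

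The second comparison, spermidine with inhibition against inhibition alone, asks how expression differed when spermidine was supplied. Mature neutrophil, myeloid and cell division genes were lower, and HSC identity genes were higher. S100a8 fell from 19330 CPM (SD 537) to 5945 CPM (SD 133; log2 fold change -1.70, SE 0.027, n = 3 per group). Mpo fell from 2201 to 1049 CPM (log2 fold change -1.07, SE 0.032) and Mki67, a marker of dividing cells, from 72.7 to 45.8 CPM (log2 fold change -0.66, SE 0.045). Hlf rose from 22.3 to 37.6 CPM (log2 fold change 0.75, SE 0.055) and Cdkn1c, a cell cycle inhibitor of quiescent HSCs, from 3.04 to 6.11 CPM (log2 fold change 1.02, SE 0.15).

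There were 4213 genes higher and 4183 lower (edgeR, adjusted p under 0.05), of which 1366 and 469 changed at least 2-fold. The libraries did not overlap for 62.8% of genes, where chance gives 10%. Leaving out immunoglobulin, other-cell and receptor genes gave 3874 higher and 3849 lower. The balance depends on the scaling, with 7711 higher and 1793 lower when libraries were scaled by total count alone and 4797 and 1090 with limma on log2(TPM + 1), so the counts of each list with scaling by total count are given beside the main ones.

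The 8 genes with the largest rise were Eif2s3y, Ddx3y, Vmn1r91, Or6x1, Zfp488, Or4q3, Xlr3b and Ttc8. Eif2s3y (ENSMUSG00000069049, chromosome Y, positions 1010543 to 1028847, plus strand) rose from 1.73 to 20.1 CPM (log2 fold change 3.54, SE 0.12) and Ddx3y (ENSMUSG00000069045, chromosome Y, positions 1260771 to 1286629, minus strand) from 1.56 to 14.7 CPM (log2 fold change 3.26, SE 0.12), and both lie on the Y chromosome. The other sex-linked genes tested, Kdm5d (log2 fold change 0.96, SE 0.096) and Uty (log2 fold change 0.81, SE 0.089), rose as well. Eif2s3y and Uty had effective lengths that differed by more than 0.5 on the log2 scale. The vomeronasal and olfactory receptors Vmn1r91 (log2 fold change 1.68, SE 0.12), Or6x1 and Or4q3 belong to a family in which 478 of 633 tested genes were higher and 13 lower (539 and 5 with scaling by total count). These receptors took 0.242% of counts (SD 0.00312) with spermidine and 0.107% (SD 0.00109) without, against 0.127% (SD 0.00133) in control. The 8 with the largest fall were Cstdc5, Slfn1, Stfa1, Arg2, Lrg1, Mapk13, Ifitm6 and Fpr1, from -2.28 (SE 0.14) for Cstdc5 to -1.74 (SE 0.053) for Fpr1, a formyl peptide receptor of neutrophils. Cstdc5 and Stfa1, Xlr3b and the receptors belong to families of close copies that can share reads, so their single values are uncertain.

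All 15 neutrophil granule genes fell, also with scaling by total count (median -1.60, camera adjusted p = 1.79e-11), as with Ngp (log2 fold change -1.66, SE 0.028), and the list's share of counts was 1.86% (SD 0.0373). The myeloid differentiation list had 18 lower and 1 higher of 20 (camera adjusted p = 7.52e-10), against 14 lower and 1 higher with scaling by total count, and included Lyz2 (log2 fold change -1.39, SE 0.026) and Ms4a3 (log2 fold change -1.11, SE 0.025). The monocyte list had 10 lower and none higher of 15 (9 and none; camera adjusted p = 0.00018), with Ccr2 down (log2 fold change -1.20, SE 0.052). The basophil, eosinophil and mast cell list had 11 lower and none higher of 12 (9 and none; camera adjusted p = 4.07e-06), with Prss34 down (log2 fold change -1.10, SE 0.044). In the B and plasma cell list 12 fell and 3 rose of 16 (8 and 4), which did not pass (adjusted p = 0.0822), although it did with scaling by total count (camera adjusted p = 0.00513) and with the replicate block (0.0496). Jchain (log2 fold change -1.58, SE 0.04) and Igkc (log2 fold change -1.45, SE 0.041) fell, H2-Ab1, an antigen-presenting molecule, rose (log2 fold change 0.64, SE 0.035), and immunoglobulin genes took 0.313% of counts (SD 0.0108).

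In libraries where the neutrophil granule share fell from 4.80% to 1.86% and the immunoglobulin share from 0.643% to 0.313%, HSC identity genes rose in 23 cases and fell in 1 of 32, 8 not passing (28 and 1 with scaling by total count), with a median of 0.43 (camera adjusted p = 3.22e-06). Foxo3 (log2 fold change 0.65, SE 0.034), Hoxa9 (log2 fold change 0.64, SE 0.046), Procr (log2 fold change 0.86, SE 0.12) and Mllt3 (log2 fold change 0.50, SE 0.055) rose, and Mecom did not pass (log2 fold change 0.16, SE 0.091, adjusted p = 0.153). The ageing list had 20 higher and 13 lower of 45 (26 and 8) and did not pass (adjusted p = 0.577), with Clu falling from 38.6 to 17.0 CPM (log2 fold change -1.19, SE 0.06). The direction of this list depends on the test, since camera pointed up and fry down (fry adjusted p = 0.0211). The lymphoid priming list had 14 higher and 5 lower of 23 (18 and 2) and did not pass (adjusted p = 0.0545). The megakaryocyte and platelet list had 9 higher, 4 lower and 12 not passing of 25 (18 and 3), with an adjusted camera p of 0.205, and Vwf rose from 5.37 to 7.75 CPM (log2 fold change 0.51, SE 0.12) against 42.6 CPM in control.

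Cell division genes were lower in the same libraries. The mitosis list had 28 lower and 1 higher of 33 (22 and 2 with scaling by total count; camera adjusted p = 5.89e-10), with Birc5, survivin (log2 fold change -0.67, SE 0.028), and Ccnb1, cyclin B1 (log2 fold change -0.83, SE 0.037), down. The S phase list had 27 lower and none higher of 30 (13 and 3; camera adjusted p = 6.79e-09), with Rrm2, a ribonucleotide reductase subunit, down (log2 fold change -0.85, SE 0.039). Oxidative phosphorylation genes had 72 lower and none higher of 76 (31 and 14; camera adjusted p = 6.9e-17; adjusted p = 0.0697 with an estimated correlation), with a median of -0.32 that was -0.058 with scaling by total count. NRF2 targets had 21 lower and 3 higher of 32 (14 and 12; camera adjusted p = 8.46e-06), including Mgst1 (log2 fold change -0.93, SE 0.028) and the metallothionein Mt1 (log2 fold change -0.96, SE 0.031). The unfolded protein and stress list had 22 lower and 5 higher of 35 (14 and 9; camera adjusted p = 0.000208; adjusted p = 0.054 with an estimated correlation), with Manf down (log2 fold change -0.80, SE 0.026). Proteasome genes had 28 lower and 3 higher of 36 (13 and 10; camera adjusted p = 2.65e-07; adjusted p = 0.0677 with an estimated correlation).

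For 4 more lists that passed, the median turned positive with scaling by total count. Cytosolic ribosomal proteins had 63 lower and none higher of 80 (camera adjusted p = 3.91e-08; adjusted p = 0.314 with an estimated correlation), but 6 lower and 35 higher with scaling by total count, where the median turned from -0.18 to 0.077 and the call was lost (adjusted p = 0.527). Ribosome biogenesis genes had 20 lower and 2 higher of 36 (camera adjusted p = 0.000491), but 7 lower and 12 higher with scaling by total count, with the median turning from -0.20 to 0.057 and the call lost (adjusted p = 0.114). Glycolysis genes had 15 lower and 7 higher of 29 (camera adjusted p = 0.0215; adjusted p = 0.0694 with an estimated correlation), and 11 and 11 with scaling by total count, with the median turning from -0.17 to 0.09. Cholesterol genes had 12 lower and 3 higher of 27 (camera adjusted p = 0.0459; adjusted p = 0.0948 with an estimated correlation), and 4 and 12 with scaling by total count, with the median turning from -0.13 to 0.13 and the call lost (adjusted p = 0.186). That call was also lost without spermidine replicate 1 (adjusted p = 0.067) or 3 (adjusted p = 0.0534). With the strict low-count filter both the glycolysis call (adjusted p = 0.0734) and the cholesterol call (adjusted p = 0.165) were lost. Immediate-early genes, the other list that rose, had 21 higher and 3 lower of 27 (24 and 1; camera adjusted p = 8.46e-06; adjusted p = 0.054 with an estimated correlation), with Nr4a1 rising from 77.6 to 159 CPM (log2 fold change 1.04, SE 0.035).

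Sat1 fell from 424 to 306 CPM (log2 fold change -0.47, SE 0.027) and Eif5a fell (log2 fold change -0.40, SE 0.029). Smox, spermine oxidase, rose (log2 fold change 0.83, SE 0.15) and Arg2, a mitochondrial arginase, fell (log2 fold change -1.78, SE 0.17). These changes stood beside a fall of the neutrophil granule share from 4.80% to 1.86%, so they may not be changes within HSCs. The polyamine list had 9 higher and 12 lower of 29 (14 and 4 with scaling by total count) and did not pass (adjusted p = 0.414), with a median of -0.10, a mean of 0.045 and a median of 0.16 with scaling by total count. Pairs of higher and lower counts for the other lists that did not pass, with those from scaling by total count in parentheses, were 13 and 27 (24 and 11) for autophagy, 18 and 9 (20 and 4) for NF-kB signalling, and 13 and 4 (23 and 0) for chromatin regulators. They were 3 and 10 (6 and 6) for the erythroid list, 7 and 1 (8 and 0) for neural receptors, 0 and 7 (8 and 2) for mitochondrially encoded genes, and 7 and 12 (16 and 7) for adhesion. They were 7 and 4 (12 and 0) for G1 control, 4 and 5 (5 and 5) for T and NK cells, 8 and 9 (21 and 1) for type I interferon, and 3 and 5 (5 and 3) for stroma. They were 10 and 7 (13 and 3) for glucocorticoid targets, 7 and 7 (16 and 5) for fatty acid oxidation, and 9 and 10 (11 and 4) for p53 targets. The adjusted camera p of these 14 lists ran from 0.0757 to 0.862, and medians below 0 turned positive with scaling by total count for autophagy, erythroid, mitochondrially encoded, adhesion, stroma, fatty acid oxidation and p53 genes. For fatty acid oxidation and p53 targets the medians were -0.014 and -0.018, with tests pointing down, and the means 0.0083 and 0.038. The lymphoid priming, B and plasma cell, autophagy and mitochondrially encoded lists each passed when some single library was left out, with an adjusted p between 0.0248 and 0.0497. The erythroid (adjusted p = 0.0123) and chromatin (adjusted p = 0.00568) lists passed with scaling by total count, and autophagy with the replicate block (adjusted p = 0.0464). With the strict low-count filter the lymphoid priming (adjusted p = 0.0235), megakaryocyte (adjusted p = 0.0405), NF-kB (adjusted p = 0.0394) and chromatin (adjusted p = 0.0106) lists passed. Adjusted over the list alone, counts differed for HSC identity (25 higher), ageing (21 higher), lymphoid priming (15 higher), adhesion (8 higher), immediate-early (4 lower), mitosis (29 lower), oxidative phosphorylation (73 lower) and NRF2 targets (22 lower).

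The third comparison, spermidine with inhibition against control, asks which differences from control were present when spermidine was supplied. Pf4 was at 97.3 CPM (SD 2.84) against 2673 CPM in control (log2 fold change -4.78, SE 0.034, n = 3 per group), and Klf1, a transcription factor of erythroid cells, fell from 69.4 to 1.72 CPM (log2 fold change -5.35, SE 0.10). Ngp was at 3328 CPM against 110.5 CPM (log2 fold change 4.91, SE 0.033). Hlf (log2 fold change 3.90, SE 0.082) and Procr (log2 fold change 5.81, SE 0.24) were higher than in control, and Clu (log2 fold change -0.021, SE 0.068, adjusted p = 0.781) and Mllt3 (log2 fold change -0.064, SE 0.053, adjusted p = 0.275) did not pass. With scaling by total count both lay above control (0.24 and 0.20).

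There were 5930 genes higher and 5363 lower (edgeR, adjusted p under 0.05), of which 2991 and 1766 changed at least 2-fold, and the libraries did not overlap for 79.9% of genes, where chance gives 10%. Leaving out immunoglobulin, other-cell and receptor genes gave 5408 higher and 5134 lower. With scaling by total count 7705 were higher and 3682 lower, and with limma on log2(TPM + 1) 5237 and 2255. The 8 genes with the largest rise were Tpm3-rs7, Jchain, Ddx3y, Gbp8, Meiob, Eif2s3y, Prok2 and Wfdc18, from 9.06 (SE 0.12) to 6.35 (SE 0.20). Of these Jchain, Ddx3y and Gbp8, and also Procr and Wdr12, had effective lengths that differed by more than 0.5 on the log2 scale. The 8 with the largest fall were Fbxl13, H4c12, Pdzph1, Car1, Atp1b2, Prss50, Klf1 and Parm1, from -6.69 (SE 0.15) to -5.23 (SE 0.18), and H4c12, a histone gene, varied widely within control (SD 10.5 at a mean of 18.2 CPM).

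With an estimated correlation 4 lists passed against control, at camera adjusted p-values of 0.0212 to 0.0446. The neutrophil granule list had 14 higher and 1 lower of 15 (median 4.10, camera adjusted p = 1.71e-07). The lymphoid priming list had 18 higher and 4 lower of 23 (camera adjusted p = 0.000436), with Dntt (log2 fold change 5.61, SE 0.073) and Cd27 (log2 fold change 2.37, SE 0.053) up. Ribosome biogenesis genes had 32 lower and 3 higher of 36 (26 and 3 with scaling by total count; camera adjusted p = 1.71e-07), with Wdr12 down (log2 fold change -1.03, SE 0.029). Mitosis genes had 24 lower and 4 higher of 33 (18 and 9; camera adjusted p = 0.000343), with Mki67 down (log2 fold change -0.93, SE 0.045).

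A further 12 lists passed with the preset correlation only. Counts of genes higher and lower, with those from scaling by total count in parentheses where they moved by over 10 points, were as follows. Cytosolic ribosomal proteins had none higher and 80 lower of 80 (2 and 70; camera adjusted p = 3.25e-18; adjusted p = 0.158 with an estimated correlation), and oxidative phosphorylation 1 and 70 of 76 (11 and 55; camera adjusted p = 1.79e-13; adjusted p = 0.117 with an estimated correlation). Megakaryocyte and platelet genes had 2 and 21 of 25 (4 and 18; camera adjusted p = 4.58e-06; adjusted p = 0.0628 with an estimated correlation), with Gp1bb (log2 fold change -3.79, SE 0.052) and Itga2b (log2 fold change -2.69, SE 0.077) lower. Mitochondrially encoded genes had none higher and 13 lower of 13 (1 and 11; camera adjusted p = 3.45e-05; adjusted p = 0.0982 with an estimated correlation). Type I interferon genes had 6 and 23 of 34 (9 and 18; camera adjusted p = 0.00407; adjusted p = 0.0628 with an estimated correlation), with Irf7 lower (log2 fold change -2.24, SE 0.089). The proteasome list had 4 and 26 of 36 (19 and 7; camera adjusted p = 0.00316; adjusted p = 0.204 with an estimated correlation), and with scaling by total count its median turned from -0.15 to 0.11 and its call was lost (adjusted p = 0.882), as it was with the strict low-count filter (adjusted p = 0.136).

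The HSC identity list had 22 higher and 8 lower of 32 (median 1.29, camera adjusted p = 0.0143; adjusted p = 0.0825 with an estimated correlation), with Ly6a at 94.5 CPM (log2 fold change 3.93, SE 0.051). Myeloid differentiation genes had 15 higher and 3 lower of 20 (camera adjusted p = 0.000908; adjusted p = 0.158 with an estimated correlation), with Cd34, a surface marker of progenitors, higher (log2 fold change 3.09, SE 0.06). B and plasma cell genes had 12 higher and 3 lower of 16 (camera adjusted p = 0.00584; adjusted p = 0.0806 with an estimated correlation), and T and NK cell genes 10 and 2 of 12 (camera adjusted p = 0.0352; adjusted p = 0.117 with an estimated correlation), lost with scaling by total count (adjusted p = 0.0968). Cholesterol genes had 18 and 5 of 27 (camera adjusted p = 0.0183; adjusted p = 0.092 with an estimated correlation). Adhesion genes had 16 and 7 of 26 (21 and 2; camera adjusted p = 0.0468; adjusted p = 0.117 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.0624). It was also lost when any library other than control replicate 3 or spermidine replicate 1 was left out (adjusted p = 0.0501 to 0.0711). These lists stood beside a neutrophil granule share of 1.86% against 0.157% in control and immunoglobulin genes at 0.313% against 0.0192%.

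The remaining 19 lists did not pass, with an adjusted camera p from 0.076 for neural receptors (9 higher and 2 lower of 13; 10 and 0 with scaling by total count) to 0.872 for basophil, eosinophil and mast cells (6 and 5 of 12). The erythroid list passed with scaling by total count (adjusted p = 0.0111) and with the strict low-count filter (adjusted p = 0.0373), and with that filter so did the monocyte (adjusted p = 0.0344), unfolded protein (adjusted p = 0.018) and glucocorticoid (adjusted p = 0.0256) lists. The ageing list had 25 higher and 15 lower of 45, and with fry it pointed up (fry adjusted p = 0.0122). The polyamine list had 11 higher and 13 lower of 29 (13 and 7), with a median of -0.16 against a mean of 0.066 and a median of 0.10 with scaling by total count. Sat1 stayed above control at 306 CPM (log2 fold change 1.02, SE 0.029), and Eif5a did not pass (log2 fold change 0.043, SE 0.029, adjusted p = 0.181). The median and the mean differed in sign for immediate-early genes (0.015 and -0.099, test down), autophagy (0.13 and -0.029, test up), NRF2 targets (-0.12 and 0.061, test down), G1 control (-0.024 and 0.23, test up) and the basophil list (0.12 and -0.016, test down). Adjusted over the list alone, counts differed for the megakaryocyte (3 higher), erythroid (8 higher), B and plasma cell (13 higher) and stroma (7 higher) lists.

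The last comparison asks how far the changes with inhibition were turned back with spermidine, gene by gene. Of the 10467 genes called against control with inhibition, 3818 were called the opposite way between the spermidine and inhibition groups and 2435 the same way, where independent calls would give 3039 of each. Of the genes that rose with inhibition, 2296 were called lower with spermidine against 1516 for independent calls, and of those that fell, 1522 were called higher against 1523. This split moved with scaling by total count, to 1225 against 651 and 3022 against 2773. With RLE factors it stayed near the main one, at 2413 against 1622 and 1400 against 1413. DESeq2, which changes the test as well, gave 2119 against 1025 and 1001 against 778. Among the genes at least 2-fold higher with inhibition, 878 of 2163 were called the opposite way (626 for independent calls), and the median gene returned 7.2% of its log2 change. Neutrophil granule genes are an example, since S100a9 went from 274 CPM in control to 12160 with inhibition and 4083 with spermidine. Among those at least 2-fold lower, 667 of 2027 were called the opposite way (590.5 for independent calls), with a median return of 10.2%. Pf4 is one that was not (2673, 104 and 97.3 CPM). Against control, 8549 of the 10467 genes were still called in the same direction with spermidine, and 407 had crossed to the other side. Both comparisons use the control libraries, so part of this overlap is built in. In simulations of 3 unchanged groups a mean of 0.45 of 1.35 called genes did so, too few to show how large that part is.

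Both comparisons use the inhibition libraries, which alone makes their fold changes run opposite. Across genes, which are not independent replicates, the correlation of the fold changes was -0.23, whereas 20 simulations of 3 unchanged groups with the same library sizes gave a mean of -0.50. The covariance was -0.258 against a simulated -0.0189, a difference of -0.239. Any feature particular to the inhibition libraries, whatever its source, adds negative covariance, so this difference does not measure a return with spermidine. The simulations gave a mean of 0.15 genes called in opposite ways. They held no changed genes, so that count was bound to be small and sets no expected overlap for groups that differ.

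**Figure D3:**
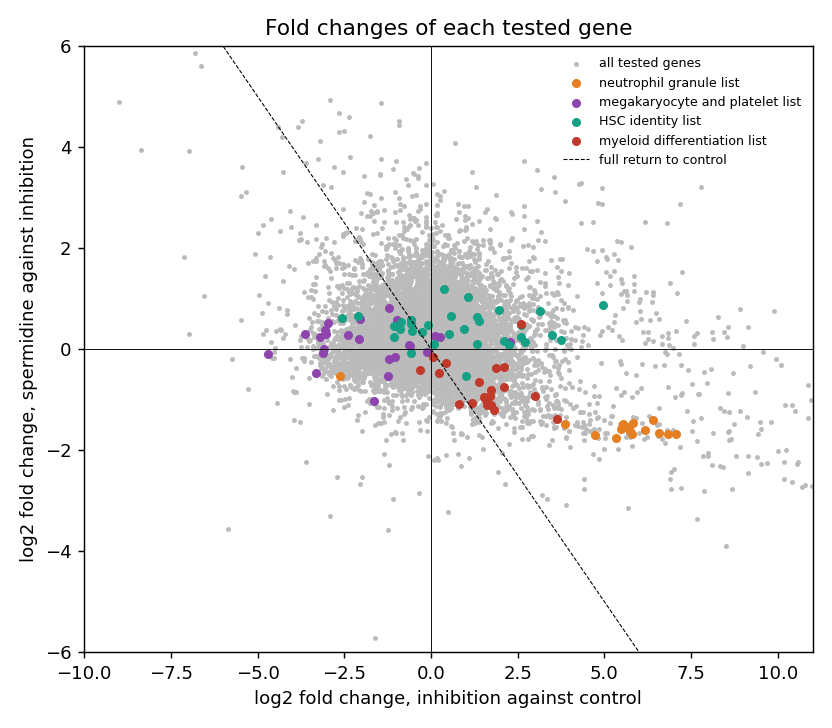
Log2 fold change of each tested gene for inhibition against control (horizontal axis) and for spermidine against inhibition (vertical axis), with 4 gene lists in colour and a dashed line where a gene would return fully to control, and genes beyond the axes not drawn. All but 1 of the 15 neutrophil granule genes lie far to the right and below 0, short of the line, and 22 of the 25 megakaryocyte genes are lower with inhibition.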

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

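Of the tests in this part, the one for genomic DNA was set out before its result was seen, and those for scaling, depth, RNA of mature cells, male share and progenitors in the gate were chosen after it. The first result lies in genes too low to be tested, where the spermidine libraries held more counts than control. Genes under the low-count filter took 0.108% of counts with spermidine (SD 0.00112), against 0.0550% in control (SD 0.00106) and 0.0576% with inhibition (SD 0.000688). Of these 4993 genes, 563 are olfactory or vomeronasal receptors, a family in which 478 of 633 tested members were higher with spermidine than with inhibition alone and 13 lower.

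Between the inhibition and spermidine groups, the tested receptor genes changed by a median of 1.08 (median absolute deviation 0.36). Scaling, which moves every gene alike, and depth are argued against, since the receptor median lay 1.06 above that of all tested genes, and the receptor share in the shallowest spermidine library (total count 16096276) was 2.26 times that in the deepest inhibition library (total count 25360256). Genomic DNA, or other reads not from mRNA, may add to the spermidine libraries and stays open. In 17 taste receptor, beta-defensin, keratin-associated and trace-amine receptor genes, usually silent in blood cells, counts went from 137 to 205 and the median rise was 0.61 (median absolute deviation 0.81), against 1.04 for the 1196 receptor genes without a filter. A response of these genes to spermidine also stays open as untested, and with inhibition against control more receptor genes were higher than lower (204 and 70, median 0.39) although their share of counts was lower (0.107% against 0.127%).

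With inhibition 14 of 15 neutrophil genes and 106 of 109 immunoglobulin genes were higher (1 of each lower, for neutrophils Cxcr2, named after its values were seen), and with spermidine all 15 and 83 were lower than with inhibition alone, 12 immunoglobulin genes being higher. Scaling is argued against for the neutrophil fall, since a factor for a library moves every gene alike and the list's median less that of all tested genes was -1.63. RNA of mature marrow cells, from neutrophils and plasma cells among the sorted cells, may be a source. For the neutrophil genes this stays open, since the test does not decide. The neutrophil median (-1.60, median absolute deviation 0.085) and the immunoglobulin median (-1.25, median absolute deviation 0.89) lay 0.35 apart. Within the wider spread lay also the medians of all 3 other lists compared, those of myeloid, monocyte and basophil genes. The most abundant genes were S100a8 (729, 19330 and 5945 CPM in control, inhibition and spermidine) and Igkc (4.54, 4029 and 1472 CPM), all 15 neutrophil genes had counts in every control library, and a sort for HSCs would usually remove such cells, but the labels name no markers. Against control the medians lay further apart (5.73, and 8.54 or 7.01 with the 54 immunoglobulin genes at 0 counts in control set at a bound of 3 counts over the group). The summed shares of counts rose by nearer factors, 30.6 for the neutrophil list and 33.6 for the immunoglobulin genes. With spermidine they were 0.388 and 0.486 of those with inhibition. Such sums rest mostly on the most abundant genes. For the neutrophil genes a change of the HSCs themselves with inhibition stays open as untested. Immunoglobulin transcripts are made by B and plasma cells, and the rise of 106 of 109 such genes, with 1 lower, argues against HSCs as their source.

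Megakaryocyte genes and erythroid genes other than haemoglobin were mostly higher in control than in both other groups. A different share of male mice stays open, since the Y-linked genes disagree. The megakaryocyte list's median absolute change between the inhibition and spermidine groups, where Ddx3y and Eif2s3y (both near 0 in control) differ, was 12.4% of that between control and inhibition (0.25 against 2.03, median absolute deviation 1.04), but Uty (88.6, 4.19 and 7.40 CPM) and Kdm5d were highest in control, as the megakaryocyte genes were. Progenitors of both lineages inside the control gate may contribute and stay open, but the test only restates the pattern. The inhibition medians were -1.66 for the megakaryocyte list and -2.35 for the 16 erythroid genes other than haemoglobin, and the whole erythroid list, at -1.22, did not pass. The 4 haemoglobin genes rose (median 2.84) and were lower again with spermidine, as Hba-a2 was (47.9, 327 and 143 CPM), like the neutrophil genes. Among HSC identity genes, Procr (0.125 CPM) and Hlf (2.50 CPM) were low in control, but Gata2 (56.4 CPM) and Mllt3 (31.5 CPM) were not. In that list 18 rose and 11 fell with inhibition, and the share of HSCs among the control cells is not known. Abundant genes of the megakaryocyte and erythroid lists were Pf4 (2673, 104 and 97.3 CPM) and Car1 (1597, 29.7 and 26.0 CPM). Of the 25 megakaryocyte genes 6 are also in the ageing list, and all 25 have counts in every library of the other groups. The labels name no gate that would remove such progenitors and no preparation batch, and an effect of inhibition on HSCs stays open as untested.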

How the results depend on the processing

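The settings with a fixed spread and the one without immunoglobulin, other-cell and receptor genes were chosen after seeing the data, and the others before. Where no cause is named, the cause was not tested. Requiring a 2-fold change, a stricter test by construction, left 2163 genes higher and 2027 lower for inhibition against control, 1366 and 469 for spermidine against inhibition, and 2991 and 1766 for spermidine against control. A spread fixed at 0.2, far wider than between these libraries, left 3314 and 3302 in the first comparison, 1806 and 899 in the second and 3187 lower in the third, and a spread of 0.1 left 2758 lower in the second. Scaling by total count gave 7711 higher and 1793 lower in the second, since it moves the median gene by 0.26. With limma on log2(TPM + 1) lower genes numbered 3427, 1090 and 2255 in the 3 comparisons, and on log2(TPM + 0.1) 3424, 1068 and 2230. Without a filter on TPM 7997 genes were higher and 1333 lower in the second and 9239 and 2918 in the third. The strict low-count filter, which tests fewer genes, gave 3918 higher in the third and a correlation of fold changes of -0.32 in place of -0.23. The other settings kept each count within 1.5 times its value.

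With an estimated correlation 10, 9 and 4 gene lists passed in the 3 comparisons, against 17, 16 and 16, and with fry, which asks another question of each list, 34, 33 and 32. Leaving out each library in turn gave 4934 to 5275 higher and 5102 to 5269 lower, then 3714 to 4323 and 3896 to 4302, then 5698 to 6047 and 5170 to 5592, with 17 to 18, 15 to 19 and 15 to 16 lists. The correlation lay between -0.26 and -0.22, moving most without inhibition replicate 2 or 3, genes called the opposite way with spermidine numbered 3451 to 3707, and those still called as in the inhibition group 8200 to 8445. With the replicate block the counts were 5199 and 5324, 4209 and 4223, and 6017 and 5484, the lists 17, 18 and 15, and the correlation -0.23.

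The log2 fold changes of named genes were recomputed as well, 3875 values for 163 results. Of these 3827 kept their direction and their side of the threshold, 32 kept their direction but no longer passed (26 with the 2-fold requirement and 6 with the spread of 0.2), 11 newly passed in the same direction and 5 reversed. The 1467 values with 1 library left out all kept both. Clu, spermidine against control, reported at -0.021, was 0.24 with scaling by total count, 0.31 on log2(TPM + 1) with and without the filter and 0.35 on log2(TPM + 0.1), and Mllt3, reported at -0.064, was 0.20 with scaling by total count, which moves the median gene by more than either value. Depth limits genes near the floor of 0.118 to 0.186 CPM, and 4993 listed genes were too low to be tested.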

Other observations

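The splits of the libraries were set out before their results were seen, and the gene groups of the next paragraph were picked after. In the polyamine list 2 transport genes fell with inhibition, while the synthesis gene Amd1 rose (SAM decarboxylase, log2 fold change 0.77, SE 0.037). Slc22a3, an organic cation transporter, fell from 86.2 to 22.4 CPM (log2 fold change -1.95, SE 0.049) and Atp13a2, which exports polyamines from lysosomes, from 30.5 to 5.96 CPM (log2 fold change -2.35, SE 0.078), and they stood at 22.3 and 7.81 CPM with spermidine. Members of the autophagy and lysosome list split, with Optn, a receptor of selective autophagy, lower (log2 fold change -3.15, SE 0.097) and Lamp2, a lysosomal membrane protein, higher (log2 fold change 1.25, SE 0.038). Tnfaip3, an inhibitor of NF-kB signalling, fell (log2 fold change -2.11, SE 0.05), and Il1r1, the receptor for interleukin-1, rose from 1.61 to 17.6 CPM and stood at 28.0 CPM with spermidine. Among chromatin regulators Sirt1, a deacetylase, fell (log2 fold change -1.44, SE 0.053) and Satb1, a genome organiser of lymphoid cells, rose (log2 fold change 2.39, SE 0.069).

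Some gene groups take a large or unusual share of the counts. Replication-dependent histone genes took 0.894% of counts in control (SD 0.0143), 0.345% with inhibition (SD 0.0124) and 0.335% with spermidine (SD 0.00657), and 56 of 60 were lower and 2 higher with inhibition, with the same counts under scaling by total count. Actb, a gene chosen after its values were seen, took 3.58% (SD 0.143), 7.93% (SD 0.757) and 5.75% (SD 0.554). Mitochondrially encoded genes took 6.93%, 4.08% and 4.38%, and cytosolic ribosomal proteins 11.5%, 8.19% and 8.94%. The Y-linked genes went different ways, Uty at 88.6, 4.19 and 7.40 CPM and Kdm5d at 13.7, 5.21 and 10.1 CPM in control, inhibition and spermidine, against 0.0755, 1.56 and 14.7 CPM for Ddx3y and 0.195, 1.73 and 20.1 CPM for Eif2s3y. The labels give no sex of the mice.

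Other splits of the 6 libraries of each comparison into 3 and 3 were fitted, 10 in all with the real one. The splits are too few for a share under 0.05. For inhibition against control the real split gave 5240 higher and 5227 lower genes and the highest other split 0. For spermidine against inhibition it gave 4213 and 4183, against 1, and for spermidine against control 5930 and 5363, against 0. Gene lists past the threshold numbered 17, 16 and 16, and the highest other split gave 14, 14 and 13. Camera with the preset correlation thus passed many lists in mixed groups with at most 1 gene called. The list counts therefore say little about this grouping. In each of the 9 results the number of splits with a result as large was 1, the real one. A split that exchanges 1 library between the groups keeps part of their difference, but it also widens the spread within each mixed group. The low gene counts of the other splits are therefore largely built in, and do not decide whether the real counts arose by chance.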
